A study of Homo sapiens with 2 samples.

How the data were processed

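Small RNA was sequenced from human cardiomyocytes derived from induced pluripotent stem cells (hiPSC-CMs), which were bought from a commercial supplier and kept for 14 days in serum-free medium. Induced pluripotent stem cells are adult cells returned to a stem cell state, from which beating heart muscle cells can be grown. Both libraries came from total RNA extracted with a column kit that retains small RNA. They were made with the Illumina TruSeq small RNA chemistry, per the labels' protocols, and read on an Illumina NextSeq instrument. The labels define 1 group with 2 replicates and do not state that the replicates were separate cultures. Any p-value between them therefore tests only whether these 2 libraries differ by more than sampling noise. Such a difference may be technical.

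Reads were mapped to the human genome build hg19 with Bowtie2, per the submitters' processing notes. The Bowtie2 version, adapter trimming, read counter and miRNA annotation release are not given in the sources used here. The deposited tables hold estimated counts, the reads at each genomic locus of a mature miRNA with no normalization, per the file headers. The counts are not all whole: 13 loci in replicate 1 and 9 in replicate 2 hold fractions of a read. The deposited tables also give RPKM, reads scaled to the listed length and the library total, together with the length of each mature miRNA. The library total behind each RPKM was recovered as reads divided by RPKM and length, and came to 3126559 reads for replicate 1 and 3100378 for replicate 2. What these totals count is not stated. Both tables hold the same 776 loci, which carry 716 mature miRNA names. Each listed locus has at least 1 read over both libraries, so a miRNA that is not listed was given neither a level nor an upper limit. At pairs of miRNAs annotated on opposite strands of the same coordinates, both entries hold equal numbers of reads. On chromosome 20, miR-103a-3p and miR-103b each hold 1339.5 reads in replicate 1, so reads may have been split evenly between the strands. Each entry may then stand below the reads at its site. miR-3184 was still counted as a hairpin of its own. The 14 loci that share coordinates are thus uncertain, among them miR-423-5p with miR-3184-3p.

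The estimated counts were summed over the loci of each name, since 51 names have several loci with the same mature sequence, and rounded to whole numbers. Levels are given as CPM of the miRNA total of the library, or as percent of that total. Intervals of 95% are Wilson intervals for shares and exact binomial intervals for ratios. Reads carry no molecular identifiers, so the intervals cover counting error only. Adapter ligation favours some small RNA ends over others in this chemistry, which limits comparisons between different miRNAs but not comparisons of the same miRNA between libraries.

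A miRNA was counted as detected at 10 CPM or more in both libraries. Replicates were compared by Pearson's r of log2(CPM + 1), by Spearman's rho, and by an exact two-sided binomial test per miRNA with at least 10 counts over both libraries. The latter was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This test compares these 2 libraries against sampling noise alone. The biological coefficient of variation was estimated with edgeR on miRNAs of at least 10 CPM in both libraries, with TMM factors. The level of a list was the median CPM of its members with reads in both libraries. It was ranked among 10000 random lists of the same size drawn from the 491 miRNAs with reads in both libraries, giving a two-sided permutation p whose smallest value is 0.0002. Adjustment ran over the 20 lists with listed members, and the outcome describes these libraries. Ratios of miRNA pairs and the share of reads on the minor arm of each hairpin were described without a test, since 2 libraries cannot give a two-sided exact sign test p below 0.5. Hairpins entered at a summed mean of 100 CPM or more with both arms listed.

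The 21 lists and 12 pairs, the tests, thresholds and the alternative settings, and the rule for named miRNAs were set before the data were examined. The rule takes the 20 most abundant miRNAs, all members of the cardiac and skeletal muscle list and the 4 most abundant members of every other list. It also takes the 5 highest and 5 lowest ratios between replicates among called miRNAs of at least 100 CPM, the pairs, and the 5 hairpins with the highest minor arm share together with those of the muscle list. The lists hold 171 names, of which 117 are listed in the tables and 54 are not. Besides muscle they cover pluripotency clusters, the chromosome 19 and 14q32 clusters, the let-7, miR-15/16, miR-17~92, miR-30, miR-29, miR-23/27/24 and miR-34 and miR-449 families, cardiac remodelling and cardiomyocyte proliferation. Markers of fibroblasts and smooth muscle, endothelium, neurons, epithelium, blood, liver and gut, and neuroendocrine and sensory cells were included, as were entries that overlap other small RNAs. A list name without its arm in the tables was matched to the name without an arm.

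The alternatives were other CPM minimums, pseudocounts and count filters, scaling by TMM or DESeq2 size factors, totals without the most abundant miRNA or without entries that overlap other small RNAs, a wider background for the lists with members at 0 kept, and leaving out each replicate. Added after the data were seen were totals implied by RPKM for detection and replicate calls, the top share without the most abundant miRNA, the coefficient of variation at 1000 CPM or more, the muscle list without each member in turn, list levels with the arms of each hairpin summed, and minor arm shares with the arms summed over all copies of a hairpin.

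Coordinates are those of hg19 as the tables list them, with the end set so that the span equals the listed length. Names of hairpin and host genes come from GENCODE release 29, matched by name, since that release uses the later build GRCh38. Of the 776 loci, 739 matched 1 hairpin gene. No host gene coordinate is given.

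The statistics were tested on simulated data. With 20 draws each over 260 miRNAs, coefficients of variation of 0.05, 0.1 and 0.2 came back as 0.0506 ± 0.00402, 0.103 ± 0.00842 and 0.200 ± 0.0140 (SD). For replicate 2 against replicate 1 with sampling noise alone, the binomial test called 0.429% of 233 unchanged miRNAs. It called 34.8% of 46 miRNAs changed 1.5-fold and 81.7% of 60 changed 3-fold. With a coefficient of variation of 0.05 added, it called 10.5% of 237 unchanged miRNAs, 57.8% of 45 changed 1.5-fold and 71.2% of 59 changed 3-fold. Unchanged and changed miRNAs were adjusted together, in 1 draw per setting. The test was given the library totals from before the changes, so a shift of the totals by changed miRNAs was not simulated. Random lists of 6 miRNAs gave a p under 0.05 in 5% of 1000 draws, and lists of 6 from the 60 most abundant miRNAs in 100%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used.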

Results

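Mature miRNAs were measured by small RNA sequencing in 2 libraries of hiPSC-CMs, heart muscle cells grown from induced pluripotent stem cells, after 14 days of culture. The series sought the miRNA profile of these cells. With 1 group there is no treated or control sample, so the comparisons are between miRNAs, between preset lists and between the replicates. Replicate 1 holds 968392 miRNA reads and replicate 2 holds 1029145. These were 31.0% (95% Wilson interval 30.9 to 31.0) and 33.2% (33.1 to 33.2) of the library totals implied by RPKM, a mean of 32.1% ± 1.57 (SD, n = 2). Reads were counted for 604 miRNAs in replicate 1 and 603 in replicate 2. All means below are over the 2 libraries and errors are SDs with n = 2.

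A few miRNAs held most of the reads. miR-143-3p alone took 32.3% ± 0.218 of them, with 32.2% (Wilson interval 32.1 to 32.3) in replicate 1 and 32.5% (32.4 to 32.6) in replicate 2. It lies on chromosome 5 from 148808541 to 148808561 (hg19, plus strand), in an exon of the long noncoding RNA gene CARMN. miR-22-3p, a miRNA known to be abundant in heart muscle, followed at 11.1% ± 0.320 (chromosome 17, 1617208 to 1617229, minus strand). miR-27b-3p, in an intron of C9orf3 (chromosome 9, 97847787 to 97847807, plus strand), took 7.26% ± 0.0736. The gaps between these 3 exceeded the spread between replicates many times over. let-7a-5p took 5.55% ± 0.324 over 3 loci, miR-181a-5p 4.48% ± 0.403 over 2 loci, miR-21-5p 4.35% ± 0.347 and miR-191-5p 4.02% ± 0.0485. The order of miR-181a-5p and miR-21-5p differed between the replicates. miR-208b-3p at 3.01% ± 0.376, let-7f-5p at 2.54% ± 0.0117 and miR-26a-5p at 2.36% ± 0.0789 completed the 10 most abundant.

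**Figure D1:**
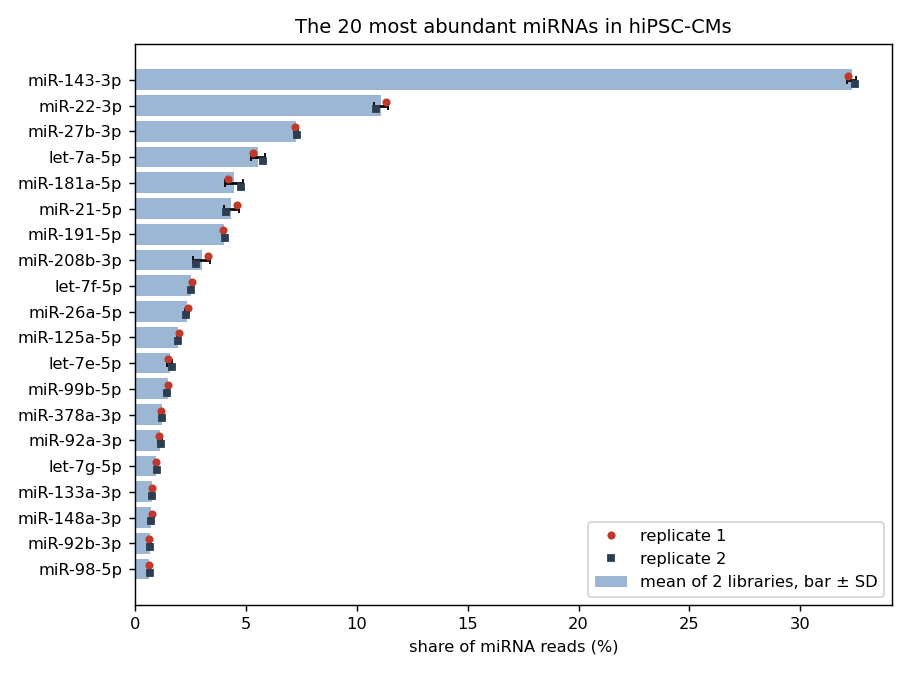
The 20 most abundant miRNAs, with the share of all miRNA reads in percent on the x axis. Bars are means of 2 libraries with SD, and the red circle and dark square are replicates 1 and 2. miR-143-3p stands at 32.3%, miR-22-3p at 11.1%, and every miRNA after miR-26a-5p lies at or below 1.96%.

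The next 10 ran from miR-125a-5p at 1.96% to miR-98-5p at 0.649%. Between them stood let-7e-5p at 1.57%, miR-99b-5p at 1.47%, miR-378a-3p at 1.20%, miR-92a-3p at 1.12% and let-7g-5p at 0.955%. miR-133a-3p, miR-148a-3p and miR-92b-3p took 0.753%, 0.735% and 0.657%. miR-378a-3p lies in an intron of PPARGC1B, a gene for a coactivator of mitochondrial metabolism (chromosome 5, 149112430 to 149112451, plus strand). Together the top 3 took 50.7% ± 0.0288 of the reads, the top 10 took 77.0% ± 0.0680, the top 20 took 88.0% ± 0.131 and the top 50 took 96.2% ± 0.112. At 10 CPM or more in both libraries 260 miRNAs were detected. Of all miRNAs, 126 reached 100 CPM, 51 reached 1000 CPM and 15 reached 10000 CPM in both.

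The muscle miRNAs, which heart or skeletal muscle expresses in a tissue-restricted way, were abundant. Of the 7 on the list, 6 were listed and all 6 reached 10 CPM in both libraries, taking 4.44% ± 0.355 of the reads. miR-208b-3p led at 30102 ± 3762 CPM and lies in an intron of MYH7, the gene of the slow beta myosin heavy chain (chromosome 14, 23887206 to 23887227, minus strand). miR-133a-3p stood at 7529 ± 61.3 CPM and miR-1 at 5536 ± 261 CPM. miR-499a-5p, in an intron of MYH7B (chromosome 20, 33578211 to 33578231, plus strand), stood at 608 ± 41.0 CPM. miR-208a-3p, in an intron of the alpha myosin gene MYH6 (chromosome 14, 23857811 to 23857832, minus strand), stood at 535 ± 66.9 CPM. miR-133b stood at 124 ± 3.20 CPM (chromosome 6, 52013786 to 52013807, plus strand), and miR-206 was not listed. Each hairpin pair of miR-1 and miR-133a sits on chromosome 18 and again on chromosome 20. The mature copies there are identical, so their reads were summed. The list's median of 3072 CPM lay at percentile 99.9 of random lists (permutation test, adjusted p = 0.0300 over 20 lists). The list's median averages miR-1 at 5536 CPM and miR-499a-5p at 608 CPM, so the call depends on the gap between them. Without any 1 of miR-208b-3p, miR-133a-3p or miR-1 the median was therefore 608 CPM, the percentile 97.8 and the adjusted p 0.147. Without any 1 of the other 3 members the median was 5536 CPM and the adjusted p 0.0140. With the arms of each hairpin summed the adjusted p was 0.0500, and it ranged from 0.00600 to 0.147 over the alternatives.

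The let-7 family, which rises as stem cells differentiate, was the other list above random lists. All 9 members reached 10 CPM in both libraries and took 12.2% ± 0.489 of the reads, with a median of 6487 CPM. The leading members were let-7a-5p at 55466 ± 3236 CPM, let-7f-5p at 25445 ± 117 CPM, let-7e-5p at 15654 ± 1148 CPM and let-7g-5p at 9546 ± 290 CPM. No random list reached its median, so its permutation p of 0.0002 is the smallest the draws can give (adjusted p = 0.0040). No list lay below random lists at an adjusted p under 0.05. The test covers only listed members with reads in both libraries, so some lists were ranked on a part of their names. The blood cell list was ranked on 2 of 8 names and the 14q32 list on 11 of 30. Members without reads in 1 or both libraries were thus left out, so the test could hardly place a list below random. The background of the test includes minor arms and had a median of 14.1 CPM, whereas the let-7 names are major arms. With the arms of each hairpin summed, the adjusted p of the let-7 list was again 0.0040. This comes from the smallest p the draws can give, so a smaller margin would not show. Minor arms named for 1 copy, such as let-7a-2-3p, still stood as hairpins of their own. The random draws also treat let-7 members as separate miRNAs, although they are related in sequence and some share a host gene.

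Further families shared by many tissues did not pass the test. The miR-23/27/24 clusters took 7.58% ± 0.0768 of the reads (adjusted p = 0.112), nearly all from miR-27b-3p, while miR-24-3p stood at 1124 ± 28.8 CPM, miR-27a-3p at 985 ± 39.1 CPM and miR-23b-3p at 766 ± 11.7 CPM. The miR-17~92 and related clusters, linked to proliferation, took 1.82% ± 0.0921 (adjusted p = 0.125), led by miR-92a-3p at 11233 ± 865 CPM, miR-25-3p at 3049 ± 45.1 CPM, miR-93-5p at 1477 ± 64.6 CPM and miR-20a-5p at 970 ± 46.0 CPM. The miR-30 family took 0.787% ± 0.0218 (adjusted p = 0.0613), with miR-30b-5p at 2721 ± 121 CPM, miR-30a-5p at 2322 ± 6.42 CPM, miR-30d-5p at 2077 ± 38.4 CPM and miR-30c-5p at 468 ± 27.9 CPM. The miR-15/16 family took 0.466% ± 0.0275 (adjusted p = 0.648), of which miR-16-5p held 4257 ± 289 CPM, against 243 ± 5.12 CPM for miR-15b-5p, 90.1 ± 1.04 CPM for miR-15a-5p and 65.9 ± 9.91 CPM for miR-424-5p. The miR-34 and miR-449 family took 0.0225% ± 0.000261 (adjusted p = 0.951), with miR-34a-5p at 212 ± 0.0958 CPM, miR-34c-5p at 12.5 ± 1.25 CPM and miR-449a at 2 reads in replicate 1 alone. The miR-29 family, whose targets include collagens, took 0.0116% ± 0.00191 (adjusted p = 0.956), with miR-29a-3p at 96.5 ± 18.3 CPM, miR-29b-3p at 13.03 ± 0.560 CPM and miR-29c-3p at 6.01 ± 0.259 CPM. The miR-17~92, miR-30, miR-23/27/24 and cardiac remodelling lists also passed with all listed miRNAs as the background and members at 0 kept, 6 lists in all. The miR-17~92, miR-30 and miR-23/27/24 lists had the same 13, 5 and 5 members under both settings, so the wider background lowered their p. The cardiac remodelling list was ranked on 7 members in place of 6, so both its background and its members changed.

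miRNAs linked to cardiac remodelling took 5.65% ± 0.326 of the reads (adjusted p = 0.171). miR-21-5p, which rises in injured heart, held 43508 ± 3469 CPM and miR-378a-3p 12030 ± 246 CPM. miR-210-3p, induced by low oxygen, stood at 527 ± 4.98 CPM and miR-23a-3p at 344 ± 24.7 CPM. miRNAs reported to drive cardiomyocyte proliferation when supplied took 0.115% ± 0.000360, with 9 of 10 listed (adjusted p = 0.951). Their most abundant members were miR-17-5p at 561 ± 5.62 CPM, miR-19b-3p at 389 ± 11.6 CPM, miR-19a-3p at 128 ± 4.10 CPM and miR-302d-3p at 25.9 ± 4.55 CPM.

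miRNAs of pluripotent stem cells took a small share of the reads. Of the 9 members of the miR-302, miR-367 and miR-371 to miR-373 clusters, 5 were listed and together took 0.00770% ± 0.00168. Their median of 20.3 CPM lay at percentile 59.6 of random lists (permutation test, adjusted p = 0.951). miR-302d-3p, miR-302b-3p, miR-302a-3p and miR-302c-3p stood at 25.9 ± 4.55, 20.6 ± 3.01, 20.3 ± 10.8 and 8.66 ± 6.74 CPM. None of the 22 chromosome 19 cluster names was listed, so no level is given for them. Of the 30 names of the imprinted 14q32 cluster 17 were listed, with 0.0145% ± 0.00122 of the reads (adjusted p = 0.726). miR-381-3p led them at 38.0 ± 4.03 CPM, ahead of miR-411-5p at 33.4 ± 7.77 CPM, miR-654-3p at 24.4 ± 3.90 CPM and miR-410-3p at 22.5 ± 2.57 CPM.

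**Figure D2:**
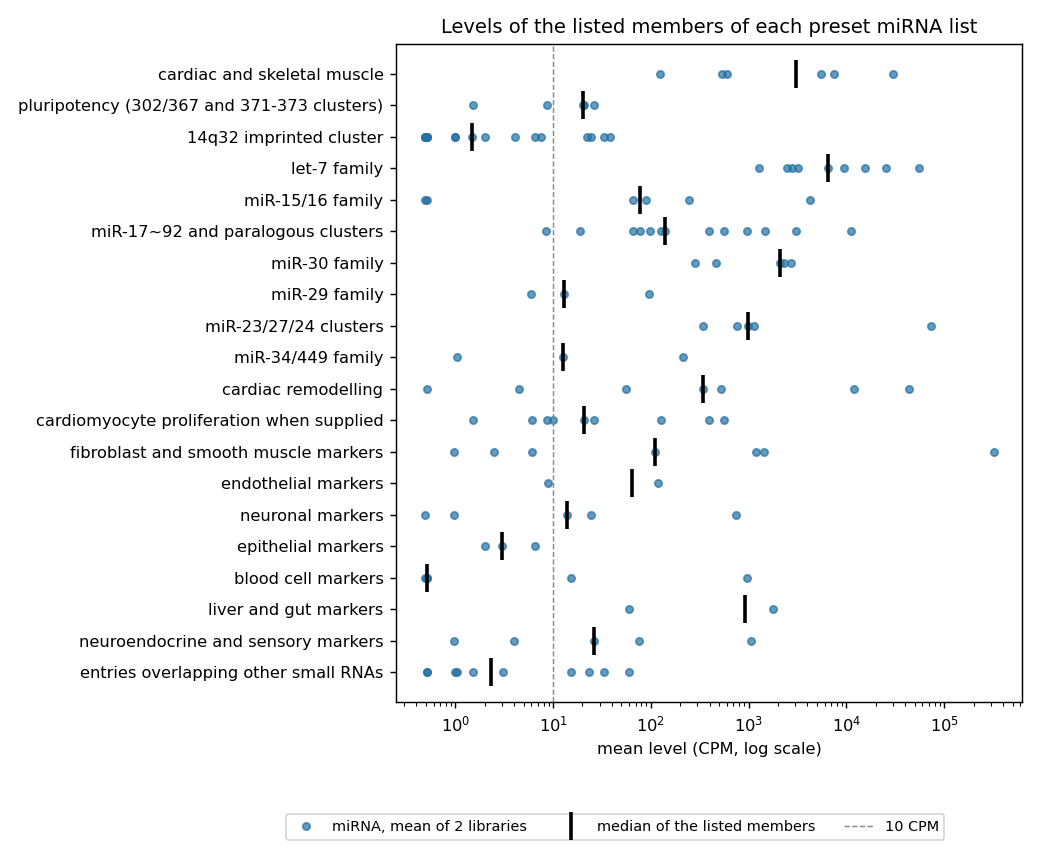
Mean CPM of every listed member of each preset list, on a log axis. Each circle is 1 miRNA (mean of 2 libraries), the black tick is the median over listed members, and the dashed line marks 10 CPM. Muscle and let-7 members all lie above 100 CPM, and miR-143-3p at 323130 CPM stands apart from the other fibroblast and smooth muscle markers.

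Markers of other cell types were uneven. The fibroblast and smooth muscle list took 32.6% ± 0.209 of the reads, nearly all from miR-143-3p, and did not pass the test (adjusted p = 0.125). Its other leading members were miR-10a-5p at 1422 ± 102 CPM, miR-145-5p at 1200 ± 19.9 CPM and miR-10b-5p at 109 ± 4.70 CPM, while miR-199a-3p stood at 6.04 ± 1.68 CPM. The endothelial list took 0.0127% ± 0.00101 (adjusted p = 0.956), with miR-126-5p at 118 ± 6.25 CPM and miR-126-3p at 8.93 ± 3.86 CPM. The neuronal list took 0.0791% ± 0.00460 (adjusted p = 0.951), with miR-128-3p at 751 ± 47.7 CPM, miR-9-5p at 24.6 ± 4.60 CPM, miR-129-5p at 14.0 ± 0.814 CPM and miR-138-5p at 2 reads in replicate 2 alone. miR-124-3p was not listed. The blood cell list took 0.0976% ± 0.00706 (adjusted p = 0.726), with miR-486-5p, also a muscle-enriched miRNA, at 960 ± 76.3 CPM. Its percentile of 78.5 rests on 2 members. With all listed miRNAs as background and members at 0 kept, the percentile was 1.19 (permutation test, adjusted p = 0.366). In this list miR-155-5p followed miR-486-5p at 15.1 ± 4.90 CPM, and miR-144-3p and miR-142-5p had 1 read each in replicate 1. miR-451a, miR-223-3p and miR-142-3p were not listed.

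The liver and gut list took 0.184% ± 0.00179 (adjusted p = 0.648), with miR-192-5p at 1780 ± 26.1 CPM and miR-194-5p at 59.2 ± 8.21 CPM. miR-122-5p, the dominant liver miRNA, was not listed. The neuroendocrine and sensory list took 0.116% ± 0.0113 (adjusted p = 0.951), with miR-182-5p at 1050 ± 105 CPM, miR-183-5p at 75.0 ± 2.44 CPM, miR-375 at 26.0 ± 3.13 CPM and miR-96-5p at 3.98 ± 1.24 CPM. The epithelial list took 0.00115% ± 2.13e-05 (adjusted p = 0.648), with miR-203a at 6.47 ± 1.85 CPM, miR-200c-3p at 3.01 ± 0.129 CPM and miR-141-3p at 3 reads in replicate 1 and 1 in replicate 2. Entries that overlap other small RNAs took 0.0139% ± 0.000526 (adjusted p = 0.956), with miR-664a-3p at 59.4 ± 8.06 CPM, miR-7977 at 33.2 ± 5.67 CPM, miR-1260b at 23.4 ± 3.95 CPM and miR-1260a at 15.1 ± 3.48 CPM.

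Pairs of related miRNAs kept nearly the same ratio in both libraries. miR-208b-3p exceeded miR-208a-3p 56.3-fold, a log2 ratio of 5.81 in each library with exact binomial intervals of 5.69 to 5.94 in both. miR-1 and miR-133a-3p, made from shared primary transcripts, differed by a log2 ratio of −0.44 ± 0.06. miR-133a-3p exceeded miR-133b by 5.93 ± 0.05. The log2 ratio of miR-499a-5p to miR-208b-3p was −5.63 ± 0.08. miR-143-3p and miR-145-5p come from 1 primary transcript and differed 269-fold (log2 8.07 ± 0.01). Other ratios were 3.80 ± 0.10 for miR-182-5p over miR-183-5p, −1.16 ± 0.08 for miR-23a-3p over miR-23b-3p, −4.32 ± 0.10 for miR-17-5p over miR-92a-3p and −5.56 ± 0.08 for miR-15a-5p over miR-16-5p. miR-302a-3p over miR-367-3p gave 3.73 ± 0.04, but from 2 and 1 reads of miR-367-3p, with intervals of 1.76 to 6.87 and 0.97 to 9.11. The pairs with miR-206 and miR-214-3p could not be computed because those miRNAs were not listed.

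Most hairpins gave reads almost entirely from 1 arm. Over 77 hairpins the median minor arm share was 2.42%. It was 1.60% in replicate 1 alone and 2.69% in replicate 2 alone. The minor arm held under 5% in 52 hairpins and over 25% in 10, and the 5p arm was the major one in 46. Arms were paired by name, so the 5p reads of all copies of miR-181a and let-7a were set against the 3p arm of only some copies. With arms summed over all copies the share of miR-181a was 11.0% ± 0.681 in place of 2.84%, and 60 of 88 hairpins lay under 5%. The arms were most even in miR-1307 (50.3% ± 5.67), miR-335 (48.6% ± 4.14), miR-106b (48.5% ± 2.14), miR-374a (46.8% ± 3.89) and miR-874 (41.4% ± 0.673). The minor arm was set by mean CPM, and it was under 50% in both libraries in 74 of the 77 hairpins. In miR-1307 it held 46.3% in replicate 1 and 54.3% in replicate 2, and in miR-335 45.7% and 51.5%. Among muscle hairpins the minor arm held 17.4% ± 0.00783 in miR-208a, 3.95% ± 0.680 in miR-133a, 0.409% ± 0.106 in miR-499a and 0.0203% ± 0.00638 in miR-208b.

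The replicates agreed closely at high levels and less at low ones. Over 716 miRNAs Pearson's r was 0.973 and Spearman's rho 0.853, across miRNAs, which are not independent replicates. All 132 miRNAs with a mean of at least 100 CPM lay within 1.5-fold between libraries, the largest difference being 1.48-fold for miR-574-3p. The biological coefficient of variation was 0.0550. The libraries still differed by more than sampling noise, with a chi-square of 7.12 per degree of freedom over 322 miRNAs (p = 4.88e-293), and were therefore not treated as 1 library deposited again. The test does not tell separate cultures from separate preparations of the same RNA. By the exact binomial test 29 of the 322 differed at an adjusted p under 0.05, with 10 higher and 19 lower in replicate 2. 59 had an unadjusted p under 0.05. This split moved with the scaling: 17 higher and 13 lower with TMM, 31 and 5 with DESeq2 size factors, and 34 and 5 with totals implied by RPKM. The test allows for sampling noise alone, and simulated libraries with a coefficient of variation of 0.05 gave calls at 10.5% of unchanged miRNAs. Those libraries also held miRNAs changed 1.5-fold and 3-fold, adjusted together with the unchanged ones, which loosens the threshold. That share, from 1 draw, therefore cannot be set directly against the 29 calls.

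**Figure D3:**
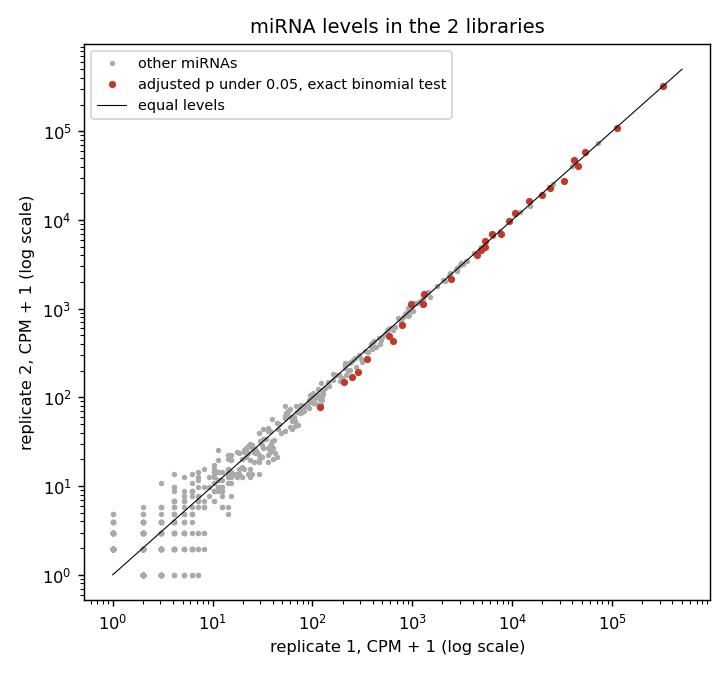
CPM + 1 of each of the 716 miRNAs in replicate 1 (x axis) and replicate 2 (y axis), both on log scales. The line marks equal levels, and red points are the 29 miRNAs with an adjusted p under 0.05 in the exact binomial test. Points spread widely below 10 CPM and stay close to the line above 100 CPM.

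Named differences between the replicates were small. The naming rule starts at 100 CPM and so leaves out miR-18a-5p (mean 98.2 CPM), the only call beyond 1.5-fold, at 0.656-fold in replicate 2. Relative to replicate 1, replicate 2 held 0.674-fold the level of miR-574-3p, 0.679-fold that of miR-374a-5p, 0.684-fold that of miR-331-3p, 0.727-fold that of miR-4485 and 0.784-fold that of miR-133a-5p. It held 1.15-fold the level of miR-182-5p, 1.14-fold that of miR-181a-5p, 1.12-fold that of miR-769-5p, 1.12-fold that of miR-92a-3p and 1.11-fold that of let-7e-5p. The TMM, DESeq2 and RPKM scalings each shift all ratios by 1 constant, so a direction could turn only near equal levels. It turned under DESeq2 and RPKM scaling for 4 of the 29, miR-22-3p, miR-26a-5p, miR-28-3p and miR-125a-5p, at 0.941-fold to 0.963-fold. miR-208b-3p and miR-208a-3p both stood at 0.838-fold in replicate 2.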

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

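The library totals behind the RPKM values exceed the reads at listed miRNA loci. On average 67.9% ± 1.57 of those totals (SD, n = 2) lay outside the loci, 69.0% in replicate 1 and 66.8% in replicate 2. This drew attention because it is a signal outside the main measurement, with 2158167 and 2071233 reads. What the totals count is not stated, the reads themselves were not analysed here, and no explanation was tested.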

How the results depend on the processing

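Values without the most abundant miRNA in the top 10 share, totals implied by RPKM, the muscle list without each member, the coefficient of variation at 1000 CPM or more, the arms summed over copies and the list levels with summed arms were chosen after the data were seen. Among alternatives of the main results, 29 stayed within the spread, within 1.5 times or on the same side of the threshold, and 12 moved. Some of the 29 could not have moved, since each of 2 libraries lies within 1 SD of their mean. Leaving out a replicate thus tested nothing for the muscle share, the miR-208b-3p to miR-208a-3p ratio and, with its members unchanged, the top 10 share. Entries that overlap other small RNAs held 0.0139% of the reads, too few to move these shares. The majority direction of the replicate calls, lower in replicate 2, turned to higher with TMM, DESeq2 and RPKM scaling (56.7%, 86.1% and 87.2% higher, against 34.5%). Detected miRNAs numbered 419 at 1 CPM and 126 at 100 CPM, by the construction of the minimum. With CPM of the larger totals implied by RPKM they numbered 183 in place of 260, which counted as within 1.5 times. With miR-143-3p left out, the top 10 share was 68.8%, as its own reads no longer counted, and the muscle share was 6.56%, as the total was smaller. The smaller total multiplied the shares of 19 lists by 1.48. Pearson's r was 0.871 with a pseudocount of 0.1, 0.996 with a pseudocount of 10 and 0.995 at 10 CPM or more in both libraries, so low counts lower it. The number of lists above random was 6 with all listed miRNAs as background and members at 0 kept, which changes the background and the members together; the cause was not tested. It was 1 without miR-208b-3p, miR-133a-3p or miR-1 and 2 without any 1 of the other 3 members of the muscle list. With the arms of each hairpin summed it was 2, the muscle list at an adjusted p of 0.0500 in a range of 0.00600 to 0.147 over its alternatives. The median minor arm share ran from 1.60% to 2.69% when either replicate was left out; the cause was not tested. With arms summed over all copies it was 2.05%.

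Calls between the replicates numbered 22 to 39 over the alternatives. Of the 29, TMM shared 23 and DESeq2 size factors 16. The DESeq2 factors were 1 in both libraries because the median ratio fell on equal counts, held by 68 of 491 miRNAs; at 100 or more counts the median ratio was 1.05, against 1.06 for the totals. No paired analysis was possible because there is only 1 group. Depth limits miRNAs under 10 CPM, where a level rests on fewer than about 10 reads per library.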

Other observations

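Tests chosen only after the result was seen are those of fibroblasts, ligation and end preference, reads exchanged between the miR-208 loci, calls at single-locus miRNAs and even sharing between copies. The tests of library totals and of genomic clusters were written before their results.

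Levels at some imprinted loci are given here as values, without a test (items chosen after their values were seen). The 27 entries of the 14q32 region, on chromosome 14 from 101488408 to 101532318 (hg19), summed to 153 ± 8.31 CPM (SD, n = 2). Entries at other imprinted loci ranged around that sum: miR-675-5p, made from the H19 transcript, had 172 ± 18.1 CPM, miR-483-5p, in an intron of IGF2, had 92.1 ± 0.286 CPM, and miR-335-5p, in an intron of MEST, had 108 ± 20.9 CPM.

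The 3p and 5p arms ranked the miR-208a and miR-208b hairpins in opposite order. Levels of their myosin host genes were not measured. On the 3p arm miR-208b exceeded miR-208a 56.3-fold, whereas on the 5p arm miR-208a had 119 and 106 reads in replicates 1 and 2 against 5 and 7 for miR-208b. The 5p ratio was 18.98-fold the other way (log2 4.25 ± 0.46), with exact binomial intervals of 9.92 to 74.6 and 7.10 to 38.6. Reads of miR-208a-3p placed at the miR-208b locus are argued against, since the mature 3p sequences differ at 3 of 22 bases. A preference of the library chemistry for particular RNA ends stays open: the minor arm shares differ 860-fold between the hairpins, and 1 chemistry cannot separate this from arm choice in the cells. No biological explanation was tested.

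miR-143-3p took 32.3% of the reads although it is best known from smooth muscle and fibroblasts. Fibroblasts in the preparation stay open: the 4 listed miR-199 miRNAs, known to be abundant in those cells, summed to 0.00373% of the miR-143-3p level, but no fibroblast profile was measured here to set against it. That subset was picked after its levels were seen, and the 6 listed members other than miR-143-3p of the preset fibroblast and smooth muscle list came to 0.848% ± 0.0323. Smooth muscle cells stay open too, with miR-145-5p at 0.371% of miR-143-3p. Ligation preference also stays open, because the 269-fold excess over miR-145-5p cannot be divided between chemistry and stability within 1 library type, and no biological explanation was tested.

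More miRNAs differed between the replicates than sampling allows. A shift of the totals by miR-143-3p alone is argued against, since 29 calls were made with totals that leave it out, 26 of them among the 29 with all miRNAs. It differed only 1.01-fold between libraries, so leaving it out could move few calls. Abundant miRNAs that differed more, such as miR-181a-5p (1.14-fold in replicate 2) and miR-208b-3p (0.838-fold), were not left out. A shift by those was not tested. Reads moving between copies of the same name are ruled out by the design, because counts were summed over these copies before the comparison. Of the calls, 22 were among 287 single-locus miRNAs, which have no other locus under their name, and 7 among 35 with several loci. Entries that share coordinates or sequence under different names were not summed, so reads moving between such entries are not ruled out. Differences in handling, RNA or library making stay open and were not tested.

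A further hypothesis held that miRNAs with identical copies had their reads shared at random. Over 25 such miRNAs with 20 or more reads in a library, the chi-square against even shares was 1.22 per degree of freedom (57 degrees, p = 0.122), as random placement would give. The reads of a copy, such as those of let-7a-5p on chromosomes 9, 11 and 22, therefore may not show which locus was transcribed.

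The hypothesis that miRNAs of a genomic cluster lie at similar levels was not borne out, but the test could not decide it. In 35 clusters of neighbours within 10 kb, with 98 hairpins of single-locus miRNAs, the mean absolute log2 difference was 4.22 against 4.30 for shuffled levels (permutation p = 0.445, 10000 permutations). This does not show that cluster members are as different as random miRNAs. Names with several loci had been left out, so a minor arm stood in for some hairpins. On chromosome 9, let-7f-1-3p with 6 reads in each library stood beside let-7d-5p with 2634 and 2891. Such gaps between arms can raise the difference within clusters.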
